A study of Mus musculus with 122 samples.

How the data were processed

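The data were junction lists from high-throughput genome-wide translocation sequencing (HTGTS), in which a known broken DNA end, the bait, is used to find the sequences, the prey, to which it was joined. The labels listed 122 samples in 35 groups, all from mouse: stimulated spleen B cells and the B lymphoma line CH12F3. The deposited values were positions and strands, with 1 row per junction, and carried no normalisation. Per the file headers, each row gave the prey chromosome, junction position and strand, the aligned span of prey and bait in the genome and in the read, and the read sequence. Per the submitters' processing notes, the authors aligned reads with Bowtie2, version not stated, to mouse genome mm9, and the labels named an altered mm9 for constructs and for the 129 strain. The labels did not state how junctions were called, whether duplicate reads were removed, or which filters were applied. Per the series text, the 3′ libraries of the allele with I-SceI sites at both Sγ1 and Sμ were analysed by the authors against different references, which gave a second file for joins in trans to Sμ. Per the labels' protocols, B cells were stimulated with αCD40 and IL4 or with LPS and αIgD-dextran, and I-SceI was added by retroviral infection 1 day after stimulation. The ATM inhibitor was given as 10 mg/ml in the labels' protocols and as 10 uM in the labels of its groups. The altered references were not available, so coordinates are those of the deposited files, on mm9 or on the altered mm9 of each group, and none were converted between references.

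All 36 files held 836378 rows, and 19 of them held chromosome 12 alone. Most files pooled the replicates of a group, so libraries were told apart by the sequencing run in the read name and by the index bases at the start of the read. This gave 119 libraries for the 122 samples of the labels. For the Myc bait, 1 block of 19476 rows repeated another block and was left out, so 3 libraries stood for 4 samples. For the residual Sμ bait in ATM-deficient cells, 2 libraries were found for 4 samples. A further 69 rows had no certain library and were left out. Rows whose bait alignment did not start within 200 bp of the usual start were left out, which removed 16254 rows (1.99%). Libraries were compared by molecule, taken as the last 15 bait bases and the first 20 prey bases around the junction, with at least 25 bases required. Libraries of 1 group that shared at least 8% of the molecules of the smaller one were joined. This joined 15 libraries to another, in 6 cases as the labels name a resequenced replicate. The other 9 are separate replicates in the labels, in 8 groups, and whether they hold the same DNA is not known. Of these, 7 had the index of their partner in another run, and 2 had another index in the same run. The joining was set after seeing the data and lowers the number of replicates below that of the labels. 1 RIF1-deficient library shared 8.86% of its molecules with a wild-type library and was left out. The remaining 103 replicates held 792711 junctions. The files carry no replicate numbers, so replicates are numbered arbitrarily within a group.

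S-region windows were called on the deposited coordinates in bins of 1 kb from wild-type libraries of the same reference and stimulation. A window was a run of bins with at least 10% of the count of its peak bin, bridging at most 1 bin, and a peak needed at least 20 junctions. Windows were named by their order along the locus, by the annotation and by 28-base matches of the reads to the reference genome NCBIM37. A join was counted as on the bait's strand when prey and bait strands were equal. Such a join is a deletion when the prey lies ahead of the bait's reading direction and an excision circle when it lies behind, and a join of opposite strands is an inversion. Junctions within 500 bp of the bait end were left out of S-region values, and junctions within 10 kb of the bait were left out of the values on spread, translocation and time. Spread was the share of junctions in the constant region that fell outside the windows. Where the rows gave bait positions on the construct alone, the bait was placed at the pile-up of junctions. Overlap and inserted bases were computed from the query positions of bait and prey: a join was direct at 0 bases, had overlap (microhomology) when the alignments shared bases, with 4 bases or more counted as long, and had inserted bases when they lay apart.

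Named features followed a rule that covered every IgH S region, the loci of a fixed list with at least 10 junctions, and 10 windows of 20 kb. The list held 26 genes or microRNAs hit by AID, the enzyme that starts breaks in S regions, or broken in activated B cells, together with Igk and Igl. Syk was not found in the annotation. Control lists were 10 long genes of neurons and the T cell receptor loci. Loci were widened by 2 kb on each side, and the expected number was the share of reference bases without N. The windows were those on other chromosomes than the bait's with the most libraries holding at least 3 junctions, and then the most junctions. The comparisons, tests, lists, windows rule and most alternatives were set before the data were examined.

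For each comparison, 1 percentage per replicate with at least 10 joins entered a two-sided exact permutation test of the difference of means, with Benjamini-Hochberg adjustment within each kind of result and a threshold of 0.05. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The effect of the inhibitor was compared between genotypes by permuting the residuals of a linear model without the interaction, 100000 times. Joins in trans were compared with 50% by a two-sided exact binomial test on pooled junctions. Loci were compared by two-sided Fisher's exact tests on pooled junctions, adjusted over 18 loci. The tests on pooled junctions compare the pooled libraries and not the conditions. Single shares have 95% Wilson intervals, and a share of 0 is given the limit of 3 counts of its total. The labels state no molecular identifiers, and repeated reads of 1 molecule could not be told from independent joins, so intervals and limits cover counting error only. Replicates held 762 to 29189 junctions.

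The steps were tested on simulated data over 200 runs, except the sharing of molecules, which was tested in 1 run. In the family of 12 comparisons with the 5′Sμ bait, simulated with a replicate SD of 2 points, a shift of 10 points was recovered in 99.55% and a shift of 3 points in 6.95%, and 0% of unchanged comparisons passed the threshold. The smallest exact permutation p of this family, 0.00794, cannot pass alone after adjustment over 12 tests. The 0% was thus largely fixed in advance and says little about false calls. This family includes DMSO against inhibitor in 53BP1-deficient cells, where 3 against 3 replicates cannot pass, so these shares cannot cover that comparison. Nor do they cover 53BP1 and RIF1 at Sε, whose replicate SDs were 8.12 and 5.57 points. For the 18 loci of the allele with 2 sites 96 kb apart, a 10-fold rise of Myc was recovered in 19% of runs for the 3′ end and in 100% for the 5′ end. A 50-fold rise was recovered in 100% for both, and at most 0.235% of unchanged loci passed. Windows of known bounds were recovered in 100% of cases. In its 1 run, a share of 10% of molecules placed in 2 libraries was recovered.

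Alternatives collapsed identical positions, changed the windows (2% of the peak, or 2 kb wider), left out 5 kb around the bait end, required prey alignments of at least 50 bp, left out the sequencing run with the most junctions, left out positions with over 1% of a library, and left out each replicate in turn. Others changed the distance around the bait (100 kb or none) for translocations, the distance from the cut (200 bp or 1 kb), the off-target window (100 kb), the denominator of junction structure, and the 53BP1-deficient libraries used. 6 alternatives were chosen after seeing the data: rows tagged by the authors as of low mapping quality left out, libraries not joined, no more libraries joined than the labels name as resequenced, the mixed RIF1 library kept, bait surroundings kept in the values on spread, and sequencing run as a block where 2 or more runs held both groups. Tags of low mapping quality were absent from the files of many groups and nearly so from 2 of the 5 wild-type 5′Sμ libraries, so compared groups were not treated alike in that alternative. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.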

Results

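Joins between a broken DNA end and the switch (S) regions of the mouse immunoglobulin heavy chain locus (IgH) were measured by HTGTS in 35 groups, in which 119 libraries gave 103 replicates. Switch regions are the repetitive stretches where AID starts the breaks of antibody class switching. The replicates held 792711 junctions, between 762 and 29189 per library. The groups had 2 to 5 replicates. The baits were breaks made by the nuclease I-SceI at inserted sites, or AID breaks in the 5′ part of Sμ. In the ΔSγ1_2xI allele, I-SceI sites replaced Sγ1, and in ΔSγ1_2xI/ΔSµ_2xI they replaced both Sγ1 and Sμ. The IgH_I-96k allele carried I-SceI sites in place of Sγ1 and near Sμ, and the cMyc-25xI allele carried a cassette of sites at Myc on chromosome 15. The line CH12F3, a B lymphoma that switches to IgA, was used with 1 site in place of Sα (ΔSα_1xI, clones 1 and 2, and a line with inverted Sμ). A CH12F3 line with a non-productive allele joined from Sμ to Sα and a shortened Sμ (ΔSµ below) was used without I-SceI. Spleen B cells with a residual Sμ, named γSµ in the titles, and unmodified spleen B cells with the 5′Sμ bait were used in the same way. Spleen B cells were stimulated with αCD40 and IL4 unless LPS and αIgD-dextran are named, and CH12F3 cells with αCD40, IL4 and TGFβ. The junction lists do not measure the targeted genes, so the genotype labels could not be checked. The labels of the H2AX-deficient 5′Sμ libraries also named the ΔSγ1_2xI allele, although these libraries held 4093 joins in the Sγ1 window.

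Joins from both ends of the same break were compared to ask whether orientation depends on the end and on the position of the prey. On the deposited coordinates of chromosome 12, IgH runs from Sμ at the high to Sα at the low end. The 5′ broken ends read toward Sα and the 3′ broken ends toward Sμ. Joins on the bait's strand are deletions for prey ahead of the bait and excision circles for prey behind it. From the ΔSα_1xI site, whose prey all lay on the Sμ side, the 3′ end of clone 1 joined to Sμ on the bait's strand in 82.8% ± 1.68 (SD, n = 3) of joins, as deletions. The 5′ end did so in 51.4% ± 1.90 (SD, n = 3), as excision circles. In clone 2 these shares were 80.5% ± 4.04 (SD, n = 3) and 55.4% ± 0.722 (SD, n = 3). For both clones the replicates did not overlap, with two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, and adjusted p = 0.175 over 21 tests. Within sequencing run 29 the shares of clone 2 were 81.6% and 55.3%, and within run 36 they were 79.9% and 55.5%. The 3′ value in run 29 is of a joined replicate that also holds a library of another run. The ends of clone 1 shared no run. At Sγ2b the order of the ends was the other way, with 55.0% ± 2.04 for the 3′ end and 69.4% ± 9.14 for the 5′ end of clone 1 (SD, n = 3 each), and 49.4% ± 2.98 and 73.6% ± 4.84 for clone 2 (SD, n = 3 each). At Sγ3 the shares were 55.4% ± 5.44 and 59.3% ± 8.10 in clone 1 (SD, n = 3 each; exact permutation p = 0.4) and 55.5% ± 5.50 and 73.5% ± 5.45 in clone 2 (SD, n = 3 each).

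AID breaks as bait gave high shares from both ends. In ΔSµ cells on day 2, joins to Sα were on the bait's strand in 94.9% ± 1.84 for the 5′ end (deletions) and 93.6% ± 2.24 for the 3′ end (excision circles; SD, n = 3 each; exact permutation p = 0.6). On day 3 they were so in 95.5% ± 0.817 and 92.3% ± 0.985 (SD, n = 3 each). The ends shared runs, and within runs 34, 35 and 39 the 3′ end differed from the 5′ end by -0.518, -1.47 and -1.77 points on day 2, and within runs 35 and 37 by -3.31 and -3.18 on day 3. With run as a block the day 2 difference was -1.25 points (exact permutation within runs, p = 0.25, the smallest possible). At Sγ3 on day 2 the 5′ and 3′ ends gave 86.1% ± 1.71 and 96.4% ± 1.2004 (SD, n = 3 each), and on day 3 they gave 90.6% ± 0.664 and 93.8% ± 7.76 (SD, n = 3 each). At Sγ2b these were 87.5% ± 1.33 and 97.3% ± 2.32 on day 2 and 86.2% ± 4.14 and 96.7% ± 5.77 on day 3 (SD, n = 3 each). From the residual Sμ after αCD40 and IL4, the 5′ end gave 90.7% ± 0.709 at Sγ1 and 95.7% ± 0.594 at Sε (SD, n = 3 each). The 3′ end gave 93.5% ± 0.234 and 86.7% ± 0.481 (SD, n = 2 each). After LPS, with 2 replicates per end, the 5′ and 3′ ends gave 92.8% and 88.0% at Sγ2b, 88.0% and 92.3% at Sγ3, and 93.2% and 79.0% at Sγ2c. From the Sγ1 site of ΔSγ1_2xI/ΔSµ_2xI, joins to Sε were on the bait's strand in 74.3% ± 2.29 for the 5′ end (SD, n = 2) and 80.6% ± 6.33 for the 3′ end (SD, n = 5; exact permutation p = 0.286). Joins to Sγ3 were so in 52.4% ± 10.5 (SD, n = 2) and 73.5% ± 13.6 (SD, n = 5; exact permutation p = 0.0952). Joins to the Sμ site were so in 48.0% and 65.1% (n = 2 each). From the I-96k site, joins within 10 kb of the other I-SceI site were so in 51.6% ± 1.22 for the 5′ end (SD, n = 2) and 57.0% ± 2.29 for the 3′ end (SD, n = 4), with exact permutation p = 0.0667, the smallest possible. None of the 21 tests passed an adjusted p of 0.05. The smallest possible p was 0.1 for 3 against 2, 0.333 for 2 against 2 and 0.0476 for 5 against 2.

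**Figure D1:**
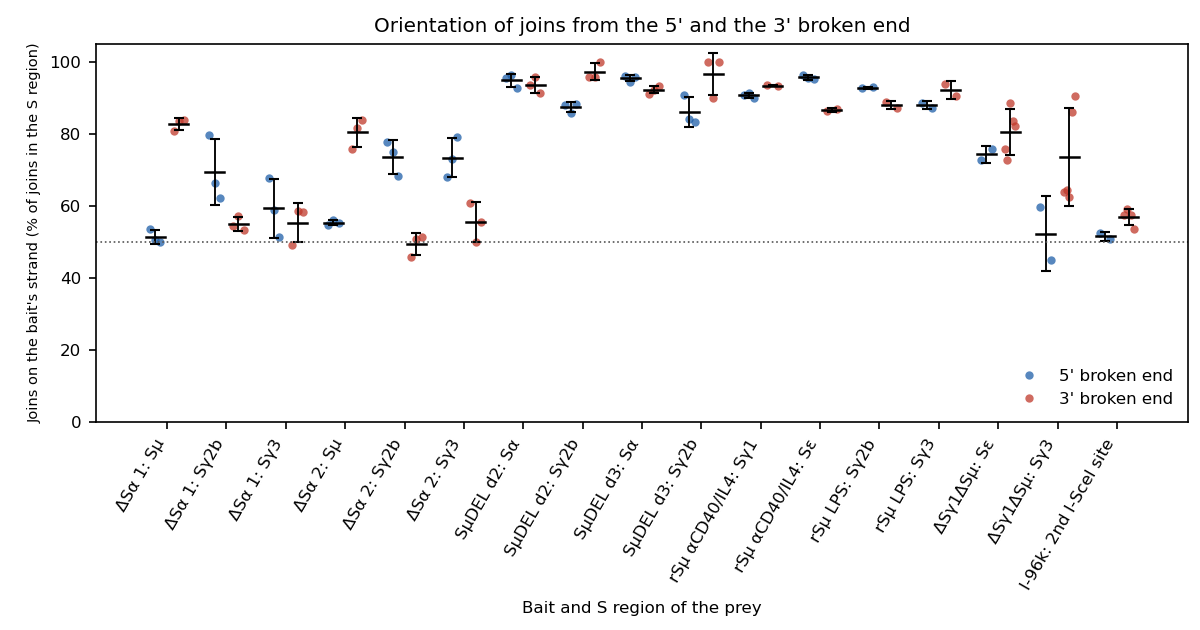
Share of joins on the bait's strand (%) for each bait and S region, with points for replicates and bars for mean ± SD, 5′ and 3′ broken ends side by side and a dotted line at 50%. The ΔSα_1xI clones show 82.8% and 80.5% at Sμ from the 3′ end against 51.4% and 55.4% from the 5′ end.

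The 5′Sμ bait was read in spleen B cells lacking a DNA damage response factor, to compare the deletional share of joins with wild-type cells. The 5′ end reads toward Sα, so joins on the bait's strand were deletions. In wild-type cells 93.2% ± 0.873 of Sγ1 joins and 94.9% ± 0.739 of Sε joins were deletions (SD, n = 5). At Sγ1 the share was lower in ATM-deficient cells at 83.2% ± 0.856 (SD, n = 3), in 53BP1-deficient cells at 74.5% ± 1.32 (SD, n = 4) and in RIF1fl/fl CD19-Cre cells, called RIF1-deficient below, at 80.5% ± 2.71 (SD, n = 3). It was also lower in wild-type cells with 10 uM ATM inhibitor, at 76.0% ± 0.670 (SD, n = 3). At Sε these groups had 88.7% ± 0.793, 58.0% ± 8.12, 85.7% ± 5.57 and 83.7% ± 1.23. Each of these 8 differences had adjusted p = 0.0268 over 12 tests (two-sided exact permutation), and every replicate of each group lay below every wild-type replicate. H2AX-deficient cells had 90.9% ± 1.94 at Sγ1 (SD, n = 3; exact permutation p = 0.0714, adjusted 0.0857) and 92.9% ± 1.39 at Sε (SD, n = 3; exact permutation p = 0.0357, adjusted 0.0476). The H2AX call at Sε rested on single replicates: leaving out any 1 replicate except wild-type replicate 5 ended it, with differences between -2.45 and -1.21 points. It also ended with identical positions collapsed, at -0.117 points, with prey alignments of at least 50 bp, at -1.23, and with the largest run left out, at -1.72. Over the alternatives its adjusted p reached 0.964 (exact permutation). The RIF1 call at Sε ended with identical positions collapsed, at -7.87 points (exact permutation, adjusted p = 0.0536). The Sγ1 difference ranged from -18.1 to -9.41 points for ATM and from -35.0 to -16.3 for 53BP1 over the alternatives, and was largest with rows tagged as of low mapping quality left out. Both 53BP1 calls ended with the largest run left out and with run as a block, for lack of replicates, at differences of the same sign. Leaving out 1 of the 3 ATM, RIF1 or inhibitor replicates raised the adjusted p to 0.0635 (exact permutation), since 5 against 2 cannot go below p = 0.0476, and the differences kept their sign. Without RIF1 replicate 3 the Sε difference was -6.99 points, and without replicate 2 it was -12.4. RIF1 joins were counted in windows called from the Myc bait libraries, and wild-type joins in windows called from the wild-type 5′Sμ libraries.

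Sequencing runs were partly shared between genotypes. The share at Sγ1 was 94.3% in wild-type and 76.2% in 53BP1-deficient cells in run 26, and 93.4% and 73.9% in run 27. It was 93.7% and 90.9% for H2AX in run 42, and 92.3% and 76.0% for the inhibitor in run 47. At Sε these pairs were 95.1% and 48.3%, 93.7% and 56.9%, 95.6% and 92.9%, and 95.1% and 83.7%. Joined replicates entered with all their libraries. The H2AX values in run 42 are thus those of the whole group and include libraries of another run. The 53BP1 values in run 26 also include libraries of other runs, so these pairs are not within 1 run alone. The ATM- and RIF1-deficient libraries shared no run with wild-type libraries, so run and genotype cannot be told apart for them. In 53BP1-deficient cells, all in run 45, the deletional share with DMSO was 72.5% ± 0.802 at Sγ1 and 64.5% ± 3.60 at Sε (SD, n = 3). With the ATM inhibitor it was 72.7% ± 2.52 and 63.8% ± 3.83 (SD, n = 3; exact permutation p = 1 and p = 0.9, smallest possible 0.1).

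**Figure D2:**
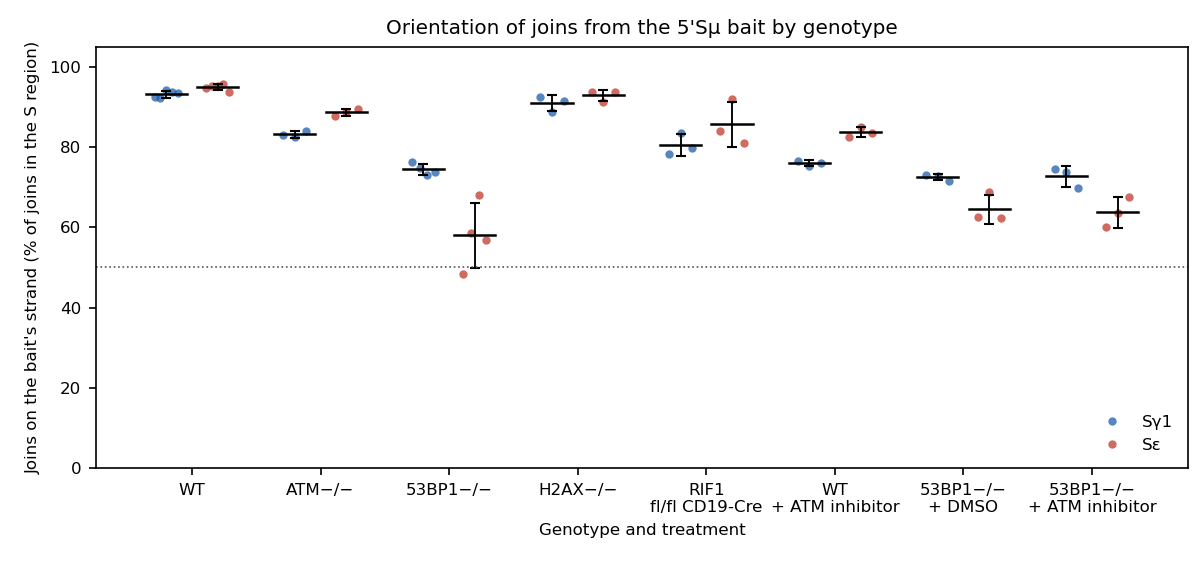
Share of joins on the bait's strand (%) from the 5′Sμ bait by genotype and treatment for Sγ1 and Sε, with points for replicates and bars for mean ± SD. At Sε the 53BP1-deficient replicates lie between 48.3% and 68.1%, below the wild-type replicates at 93.7% to 95.6%.

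The same question was asked with the I-SceI bait in place of Sγ1 and with the residual Sμ bait. From the 3′ end of ΔSγ1_2xI, 79.0% ± 5.67 of Sμ joins were on the bait's strand in wild-type cells (SD, n = 4), against 65.1% ± 11.7 in ATM-deficient cells (SD, n = 2; exact permutation p = 0.133), 47.4% ± 5.37 in 53BP1-deficient cells (SD, n = 4; exact permutation p = 0.0286, adjusted 0.0857 over 6 tests) and 77.2% ± 1.17 in H2AX-deficient cells (SD, n = 3; exact permutation p = 0.686). The ATM difference lay between -22.2 and -5.64 points when 1 replicate was left out, and was 2.83, the opposite direction, with the largest run left out. That left 1 replicate in each group, which in wild-type was replicate 4, with 70.5%. At Sε, where such joins are excision circles, the shares were 85.5% ± 4.78 (SD, n = 4), 63.7% ± 4.29 (SD, n = 2), 45.9% ± 7.09 (SD, n = 4) and 75.6% ± 4.51 (SD, n = 3). The 53BP1 replicates did not overlap the wild-type ones at either region, at the smallest p that 4 against 4 allows. The ATM and H2AX replicates overlapped wild-type at Sμ but all lay below it at Sε. Exact permutation gave p = 0.0667 for ATM at Sε, the smallest possible, and p = 0.0571 for H2AX. No test passed after adjustment. No genotype shared a run with wild-type. With the residual Sμ bait, Sγ1 deletions were 90.7% ± 0.709 in wild-type (SD, n = 3), 79.4% ± 0.132 in ATM-deficient (SD, n = 2) and 72.6% ± 3.47 in 53BP1-deficient cells (SD, n = 3). At Sε they were 95.7% ± 0.594, 86.2% ± 1.38 and 74.2% ± 1.82. No genotype shared a run with wild-type here either. In each comparison the replicates were separate, at exact permutation p = 0.1, the smallest possible.

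Spread is the share of junctions in the IgH constant region that lay outside the S-region windows. Joins to an S region without a called window count as spread. With the 5′Sμ bait, 30727 and 11666 of the 42432 wild-type joins inside windows were at Sγ1 and Sε. With the residual Sμ bait, Sγ3, Sγ2b, Sγ2c and Sα also had windows, so spread is not comparable between baits. Spread with the 5′Sμ bait was 3.46% ± 0.668 in wild-type cells (SD, n = 5). It was higher in ATM-deficient cells at 15.0% ± 1.04 (SD, n = 3), in 53BP1-deficient cells at 49.3% ± 6.18 (SD, n = 4), in H2AX-deficient cells at 34.4% ± 3.76 (SD, n = 3), in RIF1-deficient cells at 48.8% ± 4.06 (SD, n = 3) and with the ATM inhibitor at 7.34% ± 0.681 (SD, n = 3). Each had adjusted p = 0.0393 over 33 tests (two-sided exact permutation). The RIF1 windows were narrower, 5 kb at Sγ1 against 11 kb. The RIF1 coordinates are on another reference, so these windows were called from the Myc bait libraries, with 296 Sγ1 and 66 Sε joins. The wild-type windows were called from the wild-type 5′Sμ libraries that were then scored. RIF1 and wild-type values of spread, orientation and structure thus rest on windows of unlike bait and depth. The other 5′Sμ groups were scored in the wild-type windows. With the ΔSγ1_2xI and residual Sμ baits, windows also came from wild-type libraries that were then scored. This favours a low spread in wild-type cells for each bait, and the p-values do not allow for it. Over the alternatives the difference from wild-type ranged from 24.9 to 51.4 points for RIF1, with 24.9 for windows at 2% of the peak. It ranged from 6.33 to 22.3 for ATM, 33.4 to 62.7 for 53BP1, 25.7 to 46.4 for H2AX and 0.601 to 17.2 for the inhibitor. Leaving out 1 of the 3 replicates of a group ended these calls for lack of replicates, at adjusted p = 0.0748 by exact permutation. The largest run left out ended the calls of 53BP1 (50.3) and H2AX (32.2), and run as a block that of 53BP1 (50.5), also for lack of replicates. With rows tagged as of low mapping quality left out, the inhibitor difference was 0.601 points and no longer passed. The inhibitor file has no such tag. Of the wild-type libraries, the 2 of run 47 had 0.0719% and 0.0510% of rows tagged and the other 3 had 48.6% to 59.5%, so rows were left out of these 3 alone, and whether such rows had been removed from the others is not known. Within shared runs the spread was 3.22% and 54.9% for 53BP1 in run 26, 3.87% and 53.1% in run 27, 4.07% and 34.4% for H2AX in run 42, and 3.08% and 7.34% for the inhibitor in run 47. As above, the 53BP1 value in run 26 and the H2AX value in run 42 include libraries of other runs. In 53BP1-deficient cells it was 45.6% ± 2.63 with DMSO and 21.7% ± 1.68 with the inhibitor (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). That difference of -23.9 points shrank to -10.8 with tagged rows left out, which were 22.98% and 46.2% of the rows. The 53BP1-deficient file held 2 rows of chromosome 12 below the constant region and none in its lowest part, so the spread there was not measured. With the ΔSγ1_2xI bait it was 5.23% ± 1.30 in wild-type cells (SD, n = 4), 32.1% ± 2.59 in 53BP1-deficient cells (SD, n = 4) and 26.6% ± 4.19 in H2AX-deficient cells (SD, n = 3), both with adjusted p = 0.0449 by exact permutation. The H2AX call ended when any 1 replicate was left out, at differences of 18.98 to 22.74 points, and the 53BP1 call did so in 4 of 8 cases, at 25.7 to 27.7 points over all 8. Over the alternatives the differences ranged from 8.83 to 27.7 points for H2AX and from 10.8 to 28.9 for 53BP1. Each call ended in 2 of them, with rows tagged as of low mapping quality left out for both, with bait surroundings kept for H2AX (14.2) and with the largest run left out for 53BP1 (28.4). In ATM-deficient cells it was 12.7% ± 2.70 (SD, n = 2; exact permutation p = 0.0667, smallest possible), and with bait surroundings kept the difference turned to -6.97 points. With the 3 libraries that the labels name as separate replicates it was 6.85 points and passed (exact permutation, adjusted p = 0.0410, between 0.0363 and 0.213 over the alternatives). With the residual Sμ bait it was 3.61% ± 0.646 in wild-type (SD, n = 3), 7.13% ± 0.0667 in ATM-deficient (SD, n = 2) and 47.2% ± 9.25 in 53BP1-deficient cells (SD, n = 3; exact permutation p = 0.1, smallest possible).

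**Figure D3:**
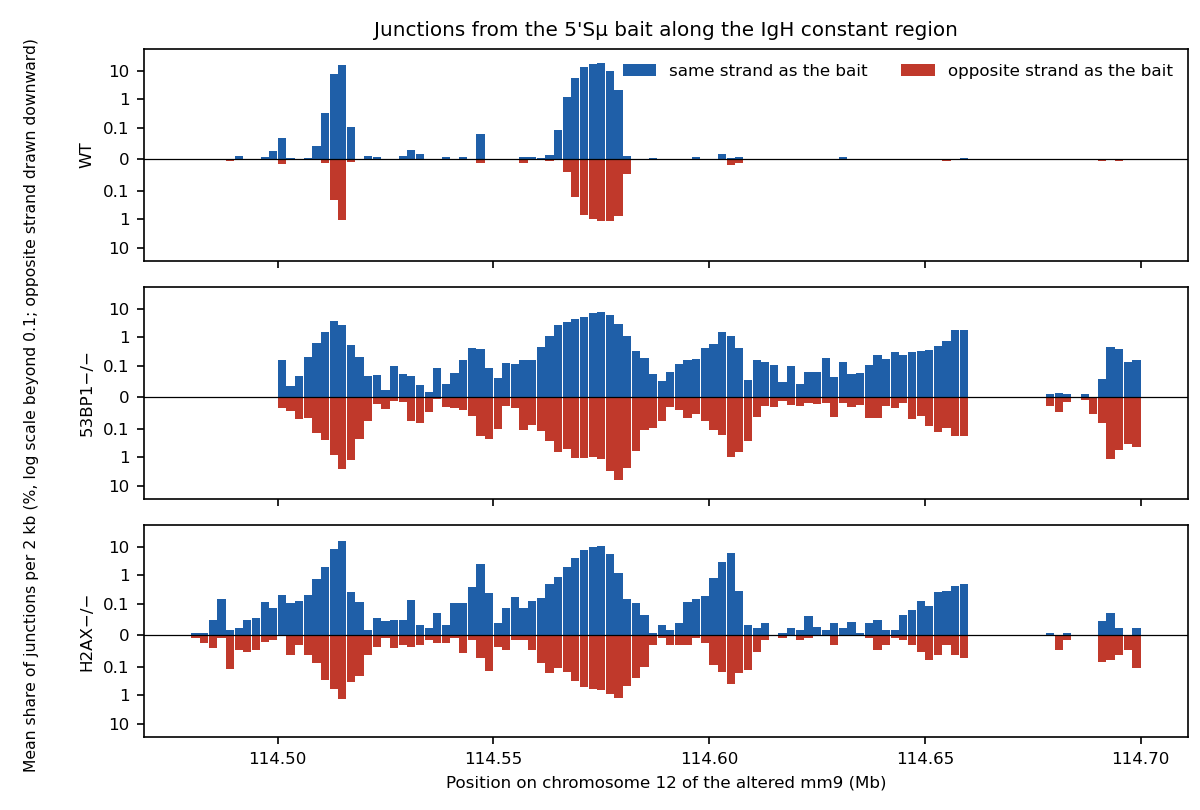
Mean share of junctions per 2 kb (%) along the IgH constant region on chromosome 12 from the 5′Sμ bait, by genotype, with the bait's strand drawn upward and the opposite strand downward. Wild-type junctions gather at Sγ1 and Sε, with 3.46% outside the windows against 49.3% in 53BP1-deficient cells.

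Junction structure was compared to ask how bait and prey were joined. Direct joins made up 23.1% ± 1.37 of S-region joins from the 5′Sμ bait in wild-type cells (SD, n = 5). Their share was 16.1% ± 1.30 in ATM-deficient, 14.8% ± 1.04 in H2AX-deficient, 13.7% ± 3.37 in RIF1-deficient and 14.9% ± 1.21 in inhibitor-treated cells (SD, n = 3 each), and 6.72% ± 0.852 in 53BP1-deficient cells (SD, n = 4). Overlaps of 4 bases or more made up 9.82% ± 1.58 in wild-type cells, and 18.7% ± 0.580, 20.5% ± 0.527, 21.6% ± 4.23, 18.4% ± 1.42 and 32.8% ± 1.32 in those groups in that order. All replicates of these groups lay on 1 side of wild-type, but adjusted p was 0.0524 over 44 tests by exact permutation, so no difference passed. With joins that have inserted bases left out of the denominator, the direct share passed in all 5 groups at adjusted p = 0.0393 by exact permutation. With libraries joined only where the labels name resequencing, it passed in all 5 at adjusted p = 0.0484 by exact permutation, and so did overlaps of 4 bases or more. Over the alternatives the adjusted p for direct joins (exact permutation) ranged from 0.0159 to 0.5 in 53BP1-deficient cells, with 0.5 for run as a block, where no test could pass. It ranged from 0.0159 to 0.171 for H2AX and from 0.0393 to 0.0561 for each of the other 3 groups. In 53BP1-deficient cells the direct share was 6.82% ± 0.295 with DMSO and 17.4% ± 0.703 with the inhibitor (SD, n = 3 each; exact permutation p = 0.1). Direct joins from ΔSγ1_2xI made up 29.6% ± 1.32 in wild-type (SD, n = 4), 22.03% ± 0.0790 in ATM-deficient (SD, n = 2), 14.8% ± 2.35 in 53BP1-deficient (SD, n = 4) and 24.8% ± 1.13 in H2AX-deficient cells (SD, n = 3). From the residual Sμ they made up 25.1% ± 0.302, 13.9% ± 0.631 and 11.4% ± 1.18 in wild-type, ATM- and 53BP1-deficient cells.

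**Figure D4:**
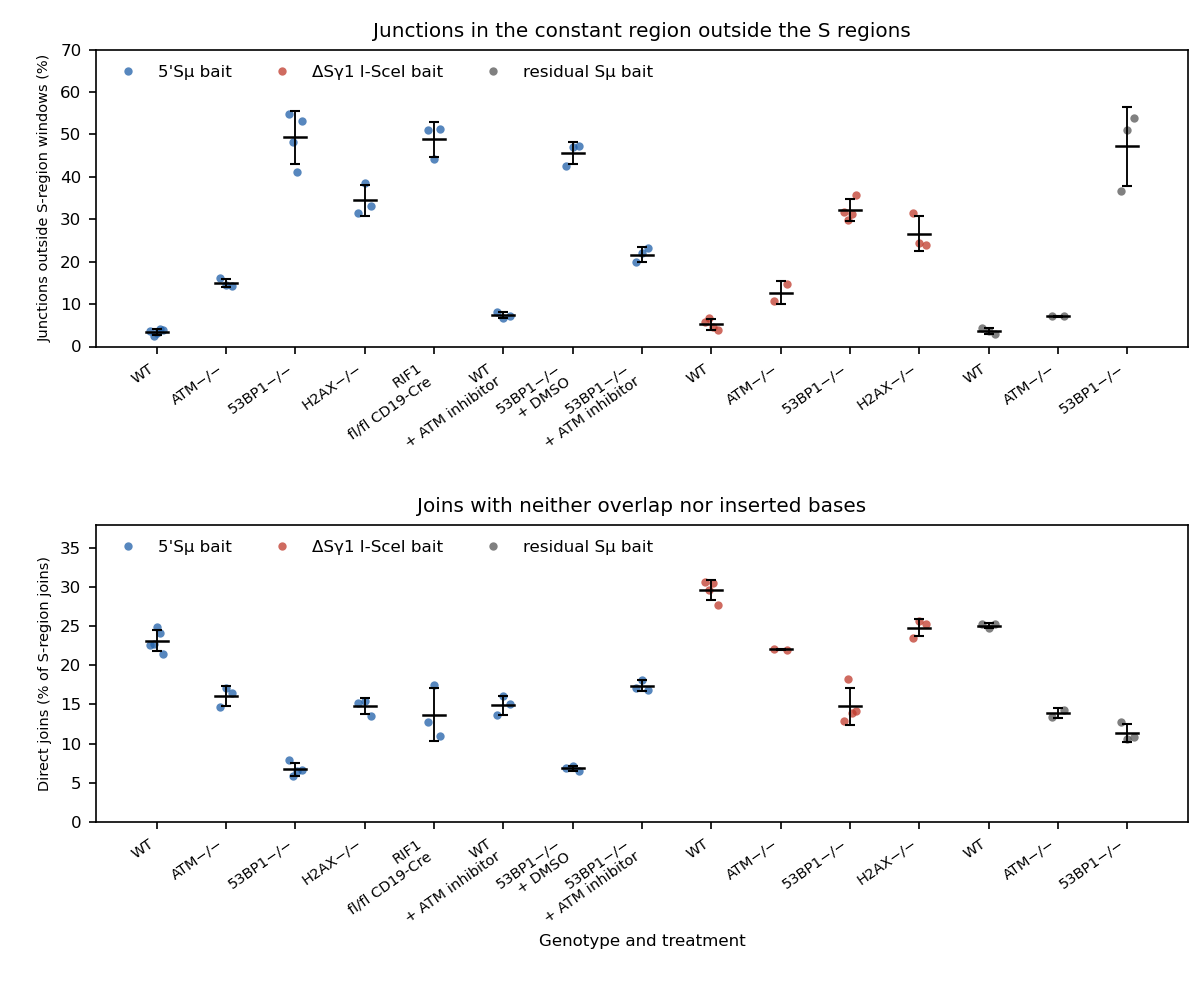
Junctions outside the S-region windows (%) and direct joins (%) from the 5′Sμ bait by genotype and treatment, with points for replicates and bars for mean ± SD. Direct joins average 23.1% in wild-type and 6.72% in 53BP1-deficient cells.

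S-region use was compared between stimulations. From the 5′ end of the residual Sμ, αCD40 and IL4 gave 59.3% ± 6.44 of S-region joins at Sγ1 and 36.1% ± 1.79 at Sε (SD, n = 3). LPS gave 61.4% ± 0.789 at Sγ2b, 24.7% ± 2.02 at Sγ2c and 12.1% ± 1.00 at Sγ3 (SD, n = 2), with 0.777% ± 1.03 at Sγ1 and 0.554% ± 0.784 at Sε. After αCD40 and IL4, Sγ2b held 2.19% ± 3.16, Sγ2c 0.872% ± 1.35 and Sγ3 1.14% ± 0.669. Replicate 1 set these minor shares in both stimulations: Sγ2b was 5.84% there and 0.296% in the lowest replicate, and after LPS Sγ1 and Sε were 1.502% and 1.11% there and 0.0516% and 0% in the other. Within run 14, Sγ2b held 2.19% after αCD40 and IL4 and 60.8% after LPS. From the 3′ end, αCD40 and IL4 gave 80.6% ± 1.18 at Sγ1 and 15.5% ± 0.615 at Sε, and LPS gave 53.0% ± 2.05 at Sγ2b, 34.4% ± 2.65 at Sγ3 and 12.1% ± 0.117 at Sγ2c (SD, n = 2). In ΔSγ1_2xI/ΔSµ_2xI, αCD40 and IL4 gave 62.8% at Sε and 35.4% at Sγ3, and LPS gave 49.9% at Sγ2b, 35.8% at Sγ3 and 14.3% at Sγ2c (n = 2 each). Each stimulation was scored in windows called from its own libraries. In this allele no Sε window was called after LPS, since a peak needed at least 20 junctions. The count of 0 of 2435 joins at Sε after LPS was thus fixed by the window rule, and fewer Sε junctions could have gone uncounted. The label of these LPS libraries names a bait at Sμ, and their junctions piled up there, whereas the αCD40 libraries were read from Sγ1, so stimulation and bait cannot be told apart. None of the 16 tests could pass, with a smallest exact permutation p of 0.1 or 0.333.

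Joins to within 10 kb of the other I-SceI site of IgH_I-96k were compared between genotypes. Joins between the 2 sites need no AID break, but joins to AID breaks of Sμ in that range were not told apart. The other site lay at 114665143 to 114665146 on the altered chromosome 12 of the I-96k reference. On the bait's strand were 57.0% ± 2.29 in wild-type (SD, n = 4) and 56.7% ± 3.42 in 53BP1-deficient cells (SD, n = 2) from the 3′ end, and 51.6% ± 1.22 and 45.7% ± 3.82 from the 5′ end (SD, n = 2 each). Within 500 bp of the cut lay 67.1% ± 7.24 and 65.4% ± 2.92 from the 3′ end (exact permutation p = 0.8), and 54.9% ± 3.13 and 43.0% ± 3.77 from the 5′ end (exact permutation p = 0.333, the smallest possible). None of the 4 tests passed.

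Inversion of Sμ in the ΔSα_1xI line tested whether orientation follows the sequence of Sμ. From the 3′ end, Sμ joins on the bait's strand made up 76.6% ± 3.30 with inverted Sμ, against 82.8% ± 1.68 in clone 1 and 80.5% ± 4.04 in clone 2 (SD, n = 3 each). In the line with inverted Sμ, 91.5% of the Sμ reads that matched the reference ran opposite to it. Sγ2b joins were so in 61.3% ± 0.684 against 55.0% and 49.4%, and Sγ3 joins in 69.5% ± 2.04 against 55.4% and 55.5%. Sμ held 38.8% ± 1.34 of the joins to Sμ, Sγ2b and Sγ3, against 86.7% ± 0.652 and 83.3% ± 2.98 (SD, n = 3 each). The Sμ share was separate from both clones at exact permutation p = 0.1, the smallest possible, and adjusted p = 0.15 over 12 tests. The inverted line was sequenced in run 46 alone, so line and run cannot be told apart.

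Joins in trans, between chromosomes, were compared with the 50% that no preferred orientation would give. From the Myc bait, 54.5% of 501 Sμ joins (Wilson 95% interval 50.1% to 58.8%), 56.4% of 296 Sγ1 joins and 37.9% of 66 Sε joins lay on the plus strand. The strand of the Myc bait was not set, so these shares are not relative to the bait. Together these were 53.9% of 863 joins (two-sided exact binomial p = 0.0246, adjusted 0.0522 over 5 tests). With prey alignments of at least 50 bp all 4 Myc values passed, with Sε -13.5 points from 50% and the others above it (exact binomial, adjusted p = 0.0458). The Sμ share depended on single replicates: without replicate 1 it lay -0.909 points from 50%, and without replicate 3 it lay 7.14 points above with adjusted p = 0.0135 by the exact binomial test. In the file for joins in trans to Sμ from ΔSγ1_2xI/ΔSµ_2xI, 44.3% of 1298 joins had the bait's strand (exact binomial p = 4.42e-05, adjusted 0.000221). The 4 libraries of that file had 30%, 45.3%, 44.9% and 64.3%, so the pooled difference from 50% did not hold in each library.

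Time after activation was compared in the ΔSµ line. Sα held 68.9% ± 7.99 of the joins on day 2 and 66.4% ± 13.3 on day 3 from the 5′ end (exact permutation p = 0.8), and 53.0% ± 6.03 and 33.8% ± 11.9 from the 3′ end (SD, n = 3 each; exact permutation p = 0.2). Within run 35 the shares were 59.7% and 51.2%, and 46.1% and 25.1%. None of the 6 tests passed, with a smallest possible p of 0.1. The share of junctions on other chromosomes was 18.3% ± 7.09 and 22.1% ± 15.2 from the 5′ end, and 28.8% ± 10.4 and 53.9% ± 15.6 from the 3′ end (SD, n = 3 each). It was 38.8% ± 13.02 in wild-type (SD, n = 4) and 42.3% ± 9.71 in 53BP1-deficient I-96k cells (SD, n = 2) from the 3′ end, and 57.4% ± 9.25 and 52.9% ± 12.6 from the 5′ end (SD, n = 2 each). In the ΔSα_1xI line it was 23.2% ± 4.01 and 23.5% ± 11.9 in clones 1 and 2 and 13.7% ± 2.03 with inverted Sμ (SD, n = 3 each), but with 100 kb around the bait left out the inverted line was 1.56 and 0.781 points above clones 1 and 2. None of these 8 tests passed.

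Junctions at off-target loci were counted in the 17 groups whose files held all chromosomes, 76096 junctions in 50 replicates. Positions are those of the deposited files, named with the annotation of NCBIM37. The loci listed for AID or B cell breaks held 1063 junctions, 4.33 times the 246 expected from their length, with 18 of 27 loci at 10 or more. Long genes of neurons held 312, 0.719 times the expected number, and T cell receptor loci held 46, 0.584 times. Myc on chromosome 15 held 338 junctions in 16 of 47 replicates, 1429 times its expected number, counted without the Myc bait. Of these, 173 and 34 came from the 5′ and 3′ libraries of 53BP1-deficient I-96k cells and 104 from the 3′ libraries of ΔSγ1_2xI/ΔSµ_2xI, so this ratio and that of the list rest on few groups. Ratios were 157 for Mir142, 148 for Pim1, 94.8 for Il4ra, 48.9 for Cd83, 24.6 for Il21r, 16.6 for Il4i1, 12.1 for Bcl6 and 10.3 for Socs2. They were 4.83 for Rapgef1, 4.74 for Pax5, 2.30 for Igk, 1.99 for Pvt1, 1.75 for Foxp1, 1.62 for Ebf1, 1.57 for Igl, 1.44 for Bach2 and 1.37 for Aff3. These ratios pool groups that differ by locus. Il4ra held 34 junctions in RIF1-deficient, 30 and 8 in ΔSγ1_2xI/ΔSµ_2xI (3′ and 5′) and 16 in Myc bait libraries, and 0 in all I-96k and CH12F3 groups. Mir142 held 8 in the 3′ day 2 libraries of ΔSµ cells and 5 in the 3′ libraries of ΔSα_1xI clone 1. The window found in most replicates, 38 with at least 3 junctions, was at 98500000 to 98519999 on chromosome 2, where 46.5% of the 28-base words recur in the genome. The next in rank, on chromosome 9 at 3020000 to 3039999 and 3000000 to 3019999, had 90.9% and 94.9% recurring. In the window at 20660000 to 20679999 on chromosome 1, 88.4% of 438 junctions lay at 1 position, and in that at 47020000 to 47039999 on chromosome 19 (Nt5c2) 90.4% of 114 did so. The other 5 windows held 54 to 469 junctions.

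Pooled I-96k libraries of 53BP1-deficient and wild-type cells were compared over 18 loci by two-sided Fisher's exact tests. From the 3′ end, Myc held 34 of 2360 junctions against 1 of 5722 in wild-type (Fisher's exact test, adjusted p = 2.55e-16). From the 5′ end it held 173 of 13303 against 17 of 9812, 7.51 times the share (Fisher's exact test, adjusted p = 2.71e-23). Cd83 held 1 against 11 junctions (Fisher's exact test, adjusted p = 0.00354) and Igk 22 against 60 (adjusted p = 2.56e-07) from the 5′ end. Past the threshold were 1 locus from the 3′ end and 3 from the 5′ end, and 3 loci had an unadjusted p under 0.05 at each end. Leaving out 1 replicate gave 1 or 2 loci at the 3′ end and 2 or 3 at the 5′ end, and wild-type 3′ replicate 3 was among those whose omission gave 2. The 53BP1-deficient libraries shared no run with the wild-type libraries, so run and genotype cannot be told apart.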

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

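All tests of explanations and the test of inhibitor effects between genotypes were chosen only after the results were seen, and the search for single samples far from their group was set before. Among 43 combinations of a measure with 1 of the 6 groups of 4 or 5 replicates, 2 held a replicate far from the others by Dixon's 95% criterion. Chance finds about 1 in 20, here 2.15, and the combinations share replicates. In wild-type ΔSγ1_2xI cells, replicate 4 had 70.5% of Sμ joins on the bait's strand, and the others had 81.2% to 82.5%. Replicate 4 alone came from another sequencing run than the others, so replicate and run cannot be told apart. Its share at Sε was also the lowest, 78.5% against 86.3% to 89.0%. In 53BP1-deficient cells with the 5′Sμ bait, replicate 4 had overlaps of 1 base or more in 80.0% of joins, and the others in 76.9% to 77.3%. No explanation was tested for either.

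The change with the ATM inhibitor differed between the wild-type and the 53BP1-deficient libraries with the 5′Sμ bait. The test was the interaction term of a linear model, with residuals of the model without it permuted 100000 times, which assumes equal SDs in the 4 groups. They were unequal: without and with inhibitor, Sε had 0.739 and 1.23 in wild-type and 3.60 and 3.83 in 53BP1-deficient cells. Spread had 0.668 and 0.681 against 2.63 and 1.68, and direct joins 1.37 and 1.21 against 0.295 and 0.703. The p-values are thus approximate. This test replaced a permutation of treatment labels within genotype, which tests whether the inhibitor had any effect. Changes are in percentage points, adjusted over 5 tests. At Sγ1 the deletional share changed by -17.2 in wild-type and 0.137 in 53BP1-deficient cells, a difference of -17.4 (permutation test, adjusted p = 5e-05). At Sε the changes were -11.3 and -0.781, a difference of -10.5 (permutation test, adjusted p = 0.00281). Spread changed by 3.88 and -23.9, a difference of 27.8, and direct joins by -8.23 and 10.6, a difference of -18.8 (permutation test, adjusted p = 5e-05 for both). Overlaps of 4 bases or more changed by 8.57 and -1.17, a difference of 9.74 (permutation test, adjusted p = 0.000325). The wild-type controls had no DMSO and came partly from other runs than the treated cells, while the 53BP1-deficient cells were all in run 45. Within run 47 alone the wild-type changes were -16.3 at Sγ1, -11.4 at Sε, 4.27 in spread, -7.75 in direct joins and 9.96 in overlaps of 4 bases or more. These values argue against the mix of runs among the controls as the source of the wild-type changes. The genotypes differed in control and shared no run here, so these cannot be told apart from genotype. Rows tagged as of low mapping quality made up 46.2% with the inhibitor and 22.98% with DMSO in 53BP1-deficient cells and 14.4% in untreated wild-type cells, all but a few in 3 of 5 libraries, and the file of treated wild-type cells has no such tag. With tagged rows left out, the spread change in 53BP1-deficient cells was -10.8, with a range over the alternatives of -24.6 to -10.8. The wild-type change in spread shrank there too and no longer passed, as given above, and the difference of 27.8 was not recomputed. No explanation was tested.

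A RIF1-deficient library that was left out shared 8.86% of its molecules with 1 wild-type library. It held 6570 junctions of run 44, with 93.3% of 1427 Sγ1 joins (95% interval 91.9 to 94.5) and 89.2% of 850 Sε joins (86.9 to 91.1) on the bait's strand. The rate of shared molecules was 43.9 times the median of library pairs of this bait, and a candidate explanation is that molecules of the wild-type library are present in it. It also shared 38.8 times the median with RIF1 replicate 3, and all 3 libraries carry the same 5-base index. The labels name 1 resequenced RIF1 replicate, and this is the only RIF1 library of another run, which would account for the sharing with replicate 3 and not with the wild-type library. Against equal joins that arose independently, the highest rate among other RIF1 and wild-type pairs, for molecules found in just the 2 libraries of a pair, was 10.4% of the rate of this pair. That test was changed after a first version over all molecules, in which the next pair, the same library with another wild-type library, reached 60.1% and pairs without this library 18.9% (2.83% for molecules found in just the 2 libraries). No biological explanation was tested.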

How the results depend on the processing

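The alternatives that left out rows of low mapping quality, kept libraries unjoined, joined them only as the labels name, kept the mixed RIF1 library, kept the bait surroundings in the spread, or took sequencing run as a block were chosen after seeing the data, and the others were set before. Over all alternatives 2685 of 2989 values kept their direction and their side of the threshold, 125 no longer passed, 92 newly passed, 63 changed direction and 24 values or counts without a test moved. Where replicates are too few for any p under 0.05, as in the 16 tests of stimulation, the side of the threshold was mostly fixed in advance. The count is thus not a measure of stability. All 191 values kept both when 5 kb around the bait end or positions over 1% of a library were left out. So did the 9 values with the mixed RIF1 library kept, the 2 with DMSO-treated 53BP1 libraries alone, and the 4 each with 200 bp or 1 kb as near the cut. Differences below are in percentage points, second group minus first or mutant minus wild-type unless stated. Unless a reason is given, the cause was not tested. No paired analysis was possible because the files carry no replicate numbers, so libraries cannot be matched to the numbers of the labels. Pairing by sequencing run was possible for some comparisons.

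With identical positions collapsed, 179 of 191 values kept both. With the 5′Sμ bait, the Sε differences of H2AX (-0.117) and RIF1 (-7.87) no longer passed, and the inhibitor difference in 53BP1-deficient cells at Sγ1 was -1.45, the opposite direction. Joins in trans from Myc to Sμ (5.51 from 50%) and to all 3 regions (3.96) newly passed. Opposite directions were seen for clone 2 minus clone 1 at Sμ (0.798) and Sγ3 (-0.112) and in translocations from the 3′ end (-1.92), for inserted bases in H2AX (0.162) and inhibitor-treated cells (-0.125), and for the 5′ Sα share over time (0.189). None of these reversals passed in either setting.

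With windows at 2% of the peak the H2AX difference at Sγ1 newly passed (-3.07), and inserted bases changed direction in RIF1 (-0.115) and in 53BP1 with the residual Sμ bait (-0.292). With windows 2 kb wider, the H2AX difference at Sγ1 (-3.55) and Myc joins in trans to Sμ (4.83), Sγ1 (5.77), Sε (-12.9, the other way) and all 3 regions (3.77) newly passed, and inserted bases with the residual Sμ bait changed direction (-0.616). With prey alignments of at least 50 bp, the H2AX difference at Sε no longer passed (-1.23) and Myc joins in trans to Sμ (4.74), Sγ1 (6.68), Sε (-13.5, the other way) and all 3 regions (3.88) newly passed. Directions changed for Sγ3 by broken end in ΔSµ cells on day 3 (-0.0773), Sγ3 use by stimulation in ΔSγ1_2xI/ΔSµ_2xI (-0.493) and I-96k translocations from the 5′ end (0.872). The I-96k 3′ count of loci was 2 instead of 1.

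Leaving out the sequencing run with the most junctions kept 72 of 110 values, and gave no value where a group had no other run. Fewer replicates remained, so the 5′Sμ differences of 53BP1 at Sγ1 (-18.8) and Sε (-42.2) and of H2AX at Sε (-1.72) no longer passed, nor did the spread of 53BP1 (50.3) and H2AX (32.2) or of 53BP1 with the ΔSγ1_2xI bait (28.4). Directions changed for Sγ3 by end in clone 1 (3.33) and in ΔSµ cells on day 3 (-5.80), for Sμ in ATM-deficient ΔSγ1_2xI cells (2.83), for Sγ3 in clone 2 minus clone 1 (-8.50), and for Myc joins in trans to Sμ (-0.909). They also changed for inserted bases in H2AX (2.12), the Sα strand share over time (-0.0344) and 5′ translocations of clone 2 minus clone 1 (0.891).

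Where 2 or more runs held both groups, run was taken as a block, with labels permuted within runs. A replicate joined over runs entered with all its libraries, so its block was not of a single run. Among these was 53BP1 replicate 1 with the 5′Sμ bait. All 24 values kept their direction, and no test could pass, with a smallest possible p of 0.167, 0.25 or 0.5. So the 5′Sμ differences of 53BP1 no longer passed at Sγ1 (-18.8), Sε (-41.8) and in spread (50.5), for lack of replicates.

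With rows tagged as of low mapping quality left out, 175 of 191 values kept both. Many files have no such tag, among them those of inhibitor-treated wild-type cells, of wild-type and 53BP1-deficient ΔSγ1_2xI cells and of ATM- and 53BP1-deficient cells with the residual Sμ. There the rows were left out on 1 side alone or on neither, so these values say nothing about stability. Of the 5 wild-type 5′Sμ libraries, 3 had 48.6% to 59.5% of rows tagged and the 2 of run 47 under 0.1%, so the same holds in part for all comparisons with them. The spread with the inhibitor (0.601) and, with the ΔSγ1_2xI bait, of 53BP1 (26.9) and H2AX (27.7) no longer passed, and the H2AX difference at Sγ1 newly passed (-7.45). Directions changed for the inhibitor in 53BP1-deficient cells at Sγ1 (-1.96) and Sε (0.644), H2AX with the ΔSγ1_2xI bait at Sμ (1.81), Sα use by stimulation (-0.111), inserted bases in H2AX (2.59), and same-strand spread with the inhibitor (-0.741) and in ATM-deficient cells with the residual Sμ bait (-0.347). With bait surroundings kept, the ΔSγ1_2xI spread of H2AX no longer passed (14.2), and that of ATM changed direction over all joins (-6.97), on the bait's strand (-9.41) and on the opposite strand (-1.93). For translocations, 100 kb left out gave 1.56 and 0.781 for inverted Sμ minus clones 1 and 2, and no distance left out gave -0.464 for clone 2 minus clone 1 from the 3′ end, all opposite in direction.

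With no more libraries joined than the labels name as resequenced, 163 of 191 values kept both and 28 newly passed, at the labels' own number of replicates for the groups concerned. They were the spread of ATM with the ΔSγ1_2xI bait (6.85), and direct joins with the 5′Sμ bait in 53BP1 (-15.7), ATM (-7.07), H2AX (-8.38), RIF1 (-9.46) and inhibitor-treated cells (-8.23) and with ΔSγ1_2xI in 53BP1, ATM and H2AX, with the values of the next setting, and other measures of structure. With libraries not joined at all, resequenced libraries also count as replicates. The H2AX difference at Sγ1 newly passed (-2.36), as did the spread of ATM with the ΔSγ1_2xI bait (6.85) and of 53BP1 with the residual Sμ bait (41.0). So did direct joins with the 5′Sμ bait in 53BP1 (-15.7), ATM (-7.07), H2AX (-8.44), RIF1 (-9.46) and inhibitor-treated cells (-8.23), with ΔSγ1_2xI in 53BP1 (-14.9), ATM (-7.60) and H2AX (-4.81), and with the residual Sμ in 53BP1 (-13.5). Sγ3 in clone 2 minus clone 1 changed direction (-0.0304). With joins that have inserted bases left out of the denominator, direct joins newly passed with the 5′Sμ bait in 53BP1 (-20.9), ATM (-9.73), H2AX (-10.6), RIF1 (-11.5) and inhibitor-treated cells (-9.91), and with ΔSγ1_2xI in 53BP1 (-18.8) and H2AX (-7.72).

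Leaving out each replicate in turn kept 976 of 1102 values, and 94 no longer passed, with fewer replicates left for the test. With the 5′Sμ bait the lowest and highest differences at Sγ1 were -10.5 and -9.68 for ATM, -14.2 and -11.6 for RIF1, and -17.5 and -16.9 for the inhibitor. At Sε they were -6.66 and -5.86 for ATM, -12.4 and -6.99 for RIF1, -11.9 and -10.7 for the inhibitor, and -2.45 and -1.21 for H2AX. For spread they were 10.9 and 11.9 for ATM, 28.8 and 32.4 for H2AX, 44.1 and 47.7 for RIF1, and 3.51 and 4.17 for the inhibitor. With ΔSγ1_2xI they were 25.7 and 27.7 for 53BP1 and 18.98 and 22.74 for H2AX. Myc joins in trans lay between -0.909 and 7.14 from 50% at Sμ and between 1.47 and 5.05 over the 3 regions, and both newly passed without replicate 3. The I-96k 3′ count of loci was 1 or 2. The other ranges that crossed 0 belonged to differences that did not pass. They were -0.765 to 1.58 at Sγ1 and -2.72 to 1.30 at Sε for the inhibitor in 53BP1-deficient cells, and -1.45 to 0.603 for inserted bases in H2AX and -0.0863 to 1.13 in 53BP1 with the residual Sμ. For I-96k 3′ they were -2.70 to 2.14 for strand and -4.05 to 1.67 near the cut. For translocations they were -3.30 to 10.4 and -13.4 to 4.33 for I-96k 3′ and 5′, -4.99 to 8.33 over time, and -4.15 to 7.03 between clones. For time they were -0.436 to 1.33 in the Sα strand share and -7.04 to 5.18 in the Sα share. They were -7.90 to 0.189 for Sγ3 by end in clone 1, -2.98 to 2.92 for Sγ3 between clones, and -3.32 to 4.13 for Sγ3 use by stimulation.

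Depth limited the values with few joins: Sε joins numbered 22 to 34 per replicate in inhibitor-treated 53BP1-deficient cells.

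Of the 10 windows on other chromosomes named in the report, 10 stayed among the first 10 when 5 kb around the bait end or positions over 1% of a library were left out. Tags of low mapping quality were present in just 1 of the 17 groups counted, RIF1 (20.1%), so leaving out such rows does not test these windows. With libraries not joined, or joined only as the labels name, or windows of 100 kb 9 did, with the largest run left out 8, with identical positions collapsed 7, and with prey alignments of at least 50 bp 6.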

Other observations

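All tests in this part were chosen only after the results were seen. With the residual Sμ bait, replicate 1 of αCD40 and IL4 held joins of the S regions used after LPS. Of its 492 Sγ2b joins, 57.1% (95% interval 52.7 to 61.4) were molecules also found in LPS replicate 1, which was sequenced in the same run, and 7.72% (5.68 to 10.4) were found in LPS replicate 2, of another run. Of the 2399 Sγ2b joins of LPS replicate 2, a separate library, 11.2% were found in LPS replicate 1. The other αCD40 replicates, also of that run, had 2 of 24 (8.33%) and 4 of 30 (13.3%) Sγ2b joins and 0 of 48 and 0 of 64 Sγ3 joins found there, so the sharing was not general to the run. Carryover between these 2 replicates is a candidate explanation. The ratio of 57.1% to 11.2%, 5.11, argues against a culture that switched to both sets of S regions as the whole cause, since separate joins would meet those of LPS replicate 1 about as often as LPS replicate 2 did. LPS replicate 1 held more Sγ2b molecules (5777 against 2129), and per 1000 molecules the shares found were 9.89% and 3.63%. In the other direction, 43.3% of 187 Sγ1 joins and 39.1% of 138 Sε joins of LPS replicate 1 were found in αCD40 replicate 1. Of the joins of αCD40 replicates 2 and 3, separate libraries, 13.9% and 13.5% at Sγ1 and 4.07% and 3.53% at Sε were found there.

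In 53BP1-deficient I-96k libraries, 39.1% (95% interval 32.7 to 45.9) of 207 Myc joins lay within 100 bp of position 61818333 on chromosome 15, the position they used most. Around their own most used position, the 3′ libraries of ΔSγ1_2xI/ΔSµ_2xI held 6.73% of 104 (3.30 to 13.2). This argues against breaks spread along Myc as in those libraries. A first version compared both at position 61818333, where those libraries held 1.92%, and was replaced. The wild-type 5′ I-96k libraries held 35.3% of 17 (17.3 to 58.7) around theirs, at 61819144, so gathering is not shown to be tied to 53BP1 deficiency. Of the 53BP1-deficient joins, 5.31% (2.99 to 9.26) lay within 100 bp of the break of the Myc bait libraries, against 6.73% in the comparison libraries. A first bound of 5% for this test of carryover from the Myc bait was missed, and it was replaced by a comparison of intervals. The replacement leaves carryover open, since the comparison libraries could themselves hold carried-over joins. Position 61818333 was also picked as the most used of the same joins. Within 500 bp, 88.6% of 123 joins lay on the side that a break there would leave open, and 85.7% of 7 (48.7 to 97.4) did so in the comparison libraries. A first bound of 75% was met by both and was replaced by a comparison of intervals, so this measure leaves a break at that position open. The labels name none, and no biological explanation was tested.

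Libraries of 53BP1-deficient cells with DMSO shared molecules with 2 libraries of the other 53BP1-deficient file, 4.92% and 4.35%, or 14.02 and 11.5 times the median of library pairs. The labels give that file for pooled replicates that include DMSO-treated ones.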
